A study of Mus musculus with 6 samples.

How the data were processed

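Messenger RNA of 6 mouse liver samples was measured, 3 labelled as having a hepatocyte-specific deletion of Abca1 (HSKO) and 3 labelled as floxed controls (WT). Per the labels' protocols, libraries were made with a stranded mRNA kit and sequenced from both ends on an Illumina HiSeq. The deposited table holds a signal per gene row and library, which the authors made from gene-level reads divided by a size factor per library. The submitters' processing notes name FastQC 0.11.3, Bowtie, RSEM 1.2.9 and DESeq 1.16.0 with the mm10 build, without saying which step each served. The annotation used for counting, read filters and the strand setting are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies can therefore not be told apart, and 712 of the 29981 rows name several genes.

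Each value was divided by the value of 1 read in its library, and 100% of values came out whole within a tolerance of 0.001. The recovered reads gave the depth of each library, and median-of-ratios size factors recomputed from them equalled those of the deposited values (1.31, 1.52 and 1.77 in WT and 0.684, 0.688 and 0.752 in HSKO). A row was above 0 in some library for 13807 rows. Intervals of counts and shares are exact and, like the limit of 3 reads for a count of 0, cover counting error only, since copies made by amplification were not told apart. A chi-square per degree of freedom between libraries was 2.76 for HSKO replicates 1 and 2 and lay between 8.27 and 32.1 for the other pairs, above counting noise throughout, so each library counted once.

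The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1) over the 2750 rows with a mean of at least 10, with a mean-variance trend, HSKO minus WT, 2-sided, and Benjamini-Hochberg adjustment at 0.05. Adjusted p-values of genes are from limma unless another tool is named. The test was chosen before the data were examined, for a normalized value. Since whole reads were recovered, DESeq2 1.42.0 and edgeR 4.0.16 quasi-likelihood with TMM were run on them as alternatives and called 809 and 1285 genes. Coordinates are those of GENCODE M21 on mm10, in which 89.2% of tested rows had a match by name.

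Gene lists and cell type markers were fixed before the data were examined. Of their genes, 635 had a row of their own, 14 a row naming several genes, 3 an older symbol and 15 no match. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the 22 lists of at least 3 tested members. That minimum was set after the data were seen. Camera passed 13 of the 22 lists, all below other genes, fry passed 12, and with an estimated correlation camera passed 0.

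Named genes followed a rule set before the data were examined. It took Abca1, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap and whose higher mean was at least 50, the 4 members with the smallest p of each of 4 primary lists, up to 2 members of each other list with a call, and a few fixed genes, some of which are not reported here. Predicted genes without a symbol stayed out of the rises and falls. Rows named only by a sequence record were treated the same way, a reading of the rule settled after the data were seen. A gene named outside the rule is said to be chosen later or is a member of a list's count.

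Alternatives set beforehand were pseudocounts of 0.5 and 10, no filter, a minimum mean of 50, upper quartile scaling, quantile normalization, no trend, robust estimation, array weights, the replicate number as a block, DESeq2, edgeR and each library left out. Scaling to hepatocyte markers, scaling to total reads and camera against the fixed lists only were added after the data were seen. The procedure was tested on simulated data with 2784 genes for the comparison of HSKO with WT. It recovered 35 of 99 genes changed by a fold of 2 and 98 of 99 changed by a fold of 4, and 5 of its 138 calls were false. The simulation changed 200 genes, as many up as down, at 1 common dispersion and without a difference in library composition. Its share of false calls therefore does not cover errors from scaling or composition.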

Results

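Liver RNA was profiled by RNA sequencing in C57BL/6 mice in which the cholesterol and phospholipid transporter Abca1 was deleted in hepatocytes with an Albumin-driven Cre recombinase (HSKO, n = 3), and in floxed controls, labelled wild type (WT, n = 3). Food was withheld between 9 am and 1 pm on the day of liver collection. The libraries were shallow. Recovered reads summed to 892042, 933319 and 838637 in WT replicates 1 to 3 and to 631020, 702013 and 645064 in HSKO replicates 1 to 3. A single row of the table, BC071253, held 43.1% to 52.9% of the reads in the WT libraries and 46.2% to 57.8% in the HSKO libraries. The remaining reads numbered 419807 to 507874 in WT and 275313 to 346848 in HSKO. Values are given as deposited, in reads divided by a size factor per library, as mean ± SD over 3 libraries, and log2 fold changes are HSKO minus WT on the scale of log2(value + 1), which understates changes of low genes. The 3 samples of a group carry separate labels, but nothing in the labels ties each to its own animal, so p-values measure the spread between these samples.

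The comparison of HSKO with WT asks which hepatic transcripts differ when hepatocytes lack Abca1. Abca1 itself, on chromosome 4 from 53030787 to 53159895 in mm10, gave 20, 36 and 34 reads in the WT libraries and 2, 1 and 2 reads in the HSKO libraries. Its normalized level was 19.4 ± 4.22 in WT and 2.35 ± 0.783 in HSKO (SD, n = 3), a log2 fold change of -2.62 (SE 0.50, limma adjusted p = 0.000862). The ratio of WT to HSKO reads, corrected for size factors, was 8.31, with an exact 95% interval of 3.43 to 26.2 that covers counting error only. All 6 libraries thus matched their labels. Which exons were removed is not given in the sources used here, and the value covers reads over the whole gene.

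Scd1, Plin2, Adipor2 and Ces1d were among the transcripts that fell in HSKO livers. Scd1, the stearoyl-CoA desaturase, was at 776 ± 583 in WT and 205 ± 85.0 in HSKO, and Plin2, which coats lipid droplets, was at 98.6 ± 20.6 and 35.6 ± 9.44 (SD, n = 3). Adipor2, an adiponectin receptor, was 3.13 times lower in HSKO at 25.6 ± 8.25, and the carboxylesterase Ces1d fell from 59.7 ± 19.7 to 15.9 ± 4.93. Over the 2750 genes tested, limma called 1103 changed at an adjusted p below 0.05, of which 783 were higher and 320 lower in HSKO. The values of both groups did not overlap for 51.5% of the genes tested, where chance gives 10%.

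Among called genes whose groups did not overlap and whose higher group mean was at least 50, the other largest falls were those of Aldh1a1, Rgn, Abcc2, Mbl2 and Pon1, with log2 fold changes of -1.42, -1.41, -1.41, -1.39 and -1.36. Aldh1a1 makes retinoic acid, Abcc2 exports bilirubin conjugates and other organic anions into bile, Mbl2 is a mannose-binding lectin and Pon1 is carried on high-density lipoprotein. With Ces1d, Adipor2 and Plin2 they made up the 8 largest falls under that condition, and adjusted p ranged from 0.000549 for Adipor2 to 0.00119 for Aldh1a1. Aldh1a1 was not called with scaling to hepatocyte markers (adjusted p = 0.0537). Under the same condition, and leaving out predicted genes and rows named only by a sequence record, the 8 largest rises were those of Rad9b, Sfi1, Cep85, Hdc, Eme1, Tmem189, Fbxo22 and Pgm3. Rad9b, a DNA damage checkpoint gene, rose from 173 ± 31.7 to 828 ± 216 (SD, n = 3, log2 fold change 2.23, SE 0.25, adjusted p = 2.97e-05). Sfi1, which encodes a centrosome protein, rose from 45.3 ± 8.45 to 196 ± 42.6, and Cep85, another centrosome gene, from 2086 ± 707 to 7552 ± 2148. The Cep85 row thus lay above Fabp1, the liver fatty acid binding protein gene, at 1844 ± 99.5 in WT and 772 ± 123 in HSKO. Whether the reads of the rising rows came from the genes they name was not tested. Hdc, the histidine decarboxylase, rose from 81.8 ± 31.7 to 279 ± 48.7. The row of Tmem189 also names a second transcript, so its value is shared.

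The balance of higher and lower calls depended on how libraries were scaled. The genes called higher had 1.07 times as many raw reads in the HSKO libraries as in the WT libraries at their median, those called lower 0.229 times as many and the 13 hepatocyte markers 0.306 times as many. Hepatocyte markers took 2.89% ± 0.885 of reads in WT and 1.14% ± 0.282 in HSKO (SD, n = 3), 2.54 times less (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). The split of higher against lower calls was 580 to 703 with upper quartile scaling, 595 to 502 with quantile normalization and 684 to 601 with edgeR and TMM. With scaling to hepatocyte markers or to total reads, both chosen after seeing the data, it was 1131 to 27 and 212 to 1093. The median log2 fold change of all genes was 0.07 with the deposited scaling and shifted by -0.28, -0.09, -0.20, 0.54 and -0.68 in the order of these 5 scalings. Without WT replicate 2 the number of genes called lower was 159, and without WT replicate 3 it was 157.

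In all 6 scalings, the same 27 genes were called lower and the same 211 higher. The 27 were Abca1, Scd1, Fasn, Fads1, Me1, Idi1, Sc5d, Plin2, Fabp1, Dbi, Adipor2, Ces1d, Abcc2, Abcb11, Amacr, Pon1, Mbl2, Rgn, Slc2a2, Arrdc3, Keg1, Paqr9, Serpina10, Klkb1, Akr1a1, Akr1c14 and Lars2. Over these scalings the log2 fold change of Abca1 lay between -3.29 and -2.07, that of Fasn between -2.29 and -1.07 and that of Scd1 between -2.35 and -1.13. The count of genes that passed every scaling was made after seeing the data. Scaling to hepatocyte markers called 27 genes lower and scaling to total reads 212 higher, so 1 scaling in each direction set nearly the whole count. All 6 scalings used the same libraries and are not separate tests.

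**Figure D1:**
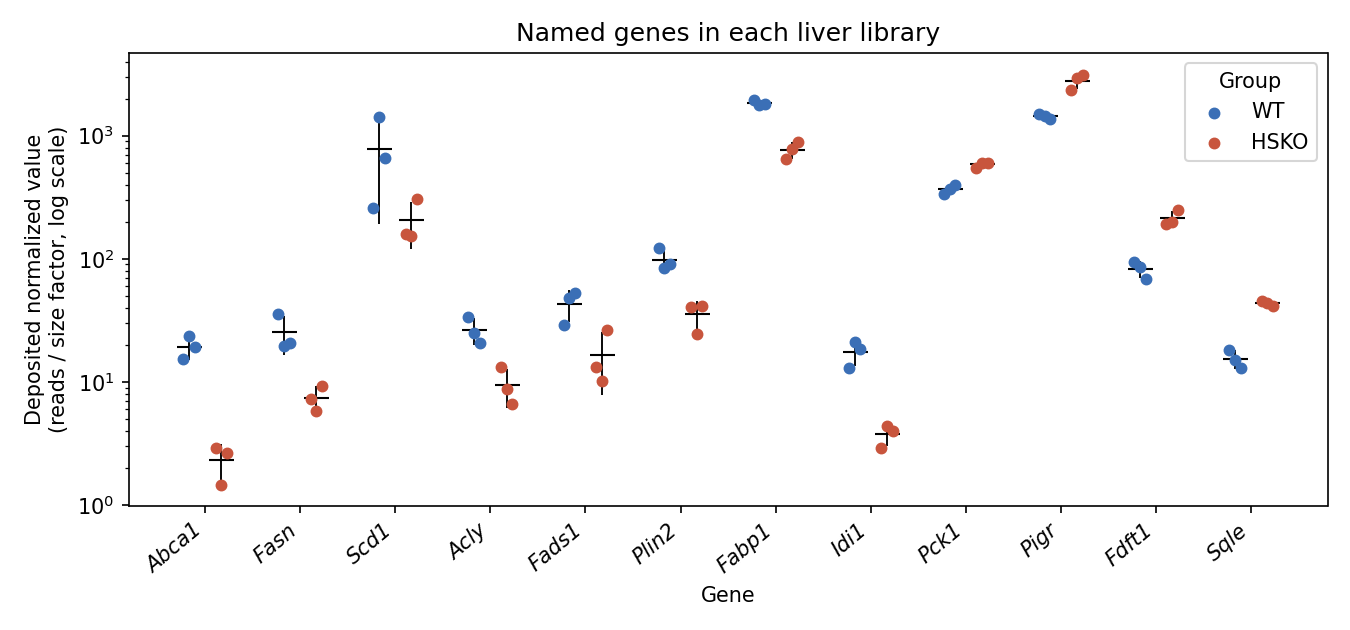
Deposited normalized values (reads divided by the size factor, log axis) of 12 named genes in each of the 3 WT and 3 HSKO libraries. Points are libraries, horizontal bars the group means and vertical lines 1 SD. Abca1 lies at 15.3 to 23.7 in WT and at 1.45 to 2.92 in HSKO, while the Scd1 values of the groups overlap.

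Most measured genes of fatty acid synthesis were lower in HSKO livers. Of the 13 measured members of the fixed list of lipogenesis and SREBP-1c targets, 8 were called lower, 0 higher and 5 neither, and all 13 log2 fold changes were below 0. Fasn, the fatty acid synthase, fell from 25.5 ± 9.00 to 7.48 ± 1.75 (SD, n = 3, log2 fold change -1.61, SE 0.35, adjusted p = 0.00165). Its raw reads were 47, 30 and 37 in WT and 5, 4 and 7 in HSKO. Acly, which makes cytosolic acetyl-CoA, fell from 26.5 ± 6.48 to 9.51 ± 3.32, and the fatty acid desaturase Fads1 from 43.4 ± 12.7 to 16.6 ± 8.75. Scd1 had a log2 fold change of -1.67 (SE 0.41, adjusted p = 0.00369), with WT libraries at 258, 1406 and 663 against 158, 154 and 303 in HSKO. Without WT replicate 2, its log2 fold change was -1.08 (adjusted p = 0.0301), and with robust estimation its adjusted p was 0.134. Adjusted over the list alone, 9 members were lower.

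The median log2 fold change of the lipogenic list was -1.10 and camera with a preset correlation placed it below other genes (adjusted p = 0.000115). The call was lost with an estimated correlation (adjusted p = 0.183) and, chosen after seeing the data, against the 230 tested members of the fixed lists only (adjusted p = 0.180). The hepatocyte markers moved the same way, with a median of -0.60 (6 of 13 lower, camera adjusted p = 0.000692, 0.286 as the adjusted p with an estimated correlation). When libraries were scaled to those markers, 4 lipogenic members remained lower, Fasn, Scd1, Me1 and Fads1, while Acly did not pass (log2 fold change -0.86, adjusted p = 0.0810). Lower lipogenic members numbered 11, 10, 11 and 13 with upper quartile scaling, quantile normalization, TMM and total reads, and 5 with DESeq2. Srebf1, which encodes SREBP-1c, was below the expression filter at 11.3 ± 4.08 in WT and 5.22 ± 1.79 in HSKO, from 18, 10 and 24 against 3, 5 and 3 reads. Without the filter its limma adjusted p was 0.218. Pnpla3 had 0 reads in all 6 libraries.

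Cholesterol synthesis genes split. Of 9 measured members of the list of cholesterol synthesis and SREBP-2 targets, 6 were lower and 2 higher, with the same counts adjusted over the list alone. The sterol desaturase Sc5d, in a row that also names a second transcript, fell from 47.1 ± 10.4 to 14.1 ± 2.17, and Idi1, the isopentenyl diphosphate isomerase, from 17.6 ± 4.15 to 3.76 ± 0.747 (SD, n = 3). Fdft1 and Sqle, which encode squalene synthase and squalene epoxidase, rose from 82.7 ± 12.8 to 213 ± 30.9 and from 15.5 ± 2.69 to 43.4 ± 2.05. The adjusted p of these 4 genes lay between 0.000652 for Sc5d and 0.00242 for Idi1, and each kept its call in all 6 scalings. Raw reads of Sqle were 24, 23 and 23 in WT and 31, 30 and 31 in HSKO. Those of Idi1 were 17, 32 and 33 in WT and 2, 3 and 3 in HSKO, so its level and SD in HSKO rest on very few reads.

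The median of the cholesterol list was -1.16 and its mean -0.72 (camera adjusted p = 0.0201, 0.237 as the adjusted p with an estimated correlation). DESeq2 gave the list an adjusted p of 0.0637, scaling to total reads 0.0720, and the fixed lists as background 0.946. With scaling to hepatocyte markers, 2 members were lower.

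Targets of the liver X receptor other than Abca1 had 1 gene higher and 1 lower, and the direction of their median depended on scaling. Among 5 measured members, Lpcat3, which remodels phospholipids, was higher at 73.7 ± 18.2 in HSKO against 40.5 ± 11.2 in WT, and Apoc1 was lower at 280 ± 50.9 against 450 ± 43.1 (SD, n = 3, adjusted p = 0.0197 and 0.0225). Both counts were the same adjusted over the list alone. The median was 0.09 and the mean 0.09, and camera did not pass the list (adjusted p = 0.846, 0.869 as the adjusted p with an estimated correlation). The median turned negative with upper quartile scaling (-0.22), quantile normalization (-0.32), TMM (-0.13) and scaling to total reads (-0.59). With scaling to hepatocyte markers it was 0.63, with 2 members higher and 0 lower, and fry passed the list (FDR 0.0335). The median of all 2750 genes tested was 0.62 with that scaling. Fry does not compare a list with other genes, so its pass does not set the LXR targets apart. Total reads gave 0 higher and 3 lower, and quantile normalization 0 higher and 2 lower. The call of Lpcat3 was lost without HSKO replicate 3 (adjusted p = 0.0825) and without WT replicate 3 (adjusted p = 0.101). That of Apoc1 was lost without HSKO replicate 1 (adjusted p = 0.106), HSKO replicate 2 (0.0824) or WT replicate 2 (0.0505). Lpcat3 also lost its call with upper quartile scaling (adjusted p = 0.0795), quantile normalization (0.108) and no filter (0.0540), and Apoc1 with no filter (0.0692) and no trend (0.0605). With scaling to total reads the log2 fold change of Lpcat3 was 0.19 (adjusted p = 0.587), and with scaling to hepatocyte markers that of Apoc1 was -0.15 (adjusted p = 0.711). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 37.5 ± 1.89 in WT and 51.8 ± 1.95 in HSKO and did not pass (adjusted p = 0.142), nor did Abcg8, at 19.8 ± 5.84 and 16.1 ± 2.85 (adjusted p = 0.522). The log2 fold change of Cyp7a1 was -0.22 with scaling to total reads and 1.00 with scaling to hepatocyte markers, where it was called (adjusted p = 0.00812). That of Abcg8 was 0.29 with scaling to hepatocyte markers, and it was called lower with scaling to total reads (adjusted p = 0.0402). Abcg1 had at most 1 read in any library, so no difference was detectable at this depth.

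In the list of gluconeogenesis and FOXO1 targets, Pck1 was called higher and Insr and Mttp lower, and the number of calls depended on scaling. Pck1, which encodes the cytosolic phosphoenolpyruvate carboxykinase, was at 366 ± 31.3 in WT and 584 ± 28.9 in HSKO (SD, n = 3, log2 fold change 0.68, SE 0.22, adjusted p = 0.0201). Insr, the insulin receptor, was lower at 9.50 ± 2.57 against 19.98 ± 3.79, and Mttp, which loads lipid onto apolipoprotein B, at 23.9 ± 6.84 against 43.2 ± 10.5 (adjusted p = 0.0238 and 0.0271). G6pc, the glucose-6-phosphatase, was at 18.9 ± 6.38 and 21.5 ± 3.87 (adjusted p = 0.588) and Apoc3 at 60.0 ± 13.2 and 37.8 ± 8.96 (adjusted p = 0.0580). Apoc3 was called lower in 4 of the 6 scalings, with adjusted p of 0.00769 in upper quartile scaling, 0.0111 in edgeR and 0.00195 with total reads, quantile normalization being the fourth, and without HSKO replicate 3 (0.0293). Of 7 measured members of the list of gluconeogenesis and FOXO1 targets, 1 was higher and 2 lower, and 2 were higher and 3 lower adjusted over the list alone. Its median was -0.37 (camera adjusted p = 0.335, 0.584 as the adjusted p with an estimated correlation), and 0.18 with scaling to hepatocyte markers, where 2 members were higher and 0 lower. With upper quartile scaling, quantile normalization and total reads, 0 were higher and 4 lower (medians -0.67, -0.75 and -1.05), and with edgeR 0 and 3 (median -0.57). Lower members numbered 0 in DESeq2, with no filter and without WT replicate 3, and 1 without WT replicate 2 or HSKO replicate 2. The log2 fold change of Pck1 was 1.22 with scaling to hepatocyte markers and -0.002 with scaling to total reads. It was not called with upper quartile scaling (adjusted p = 0.139), quantile normalization (0.968), edgeR (0.0850), no filter (0.0708) or no trend (0.0549), nor without HSKO replicate 2 (0.0867) or WT replicate 2 (0.0742). For Insr, the adjusted p was 0.133 without WT replicate 2, 0.0612 without WT replicate 3 and 0.0656 without HSKO replicate 3, and for Mttp it was 0.144 without HSKO replicate 2 and 0.138 without WT replicate 3. In DESeq2 the adjusted p of Insr was 0.119 and that of Mttp 0.0837, and with no filter they were 0.0813 and 0.0884. Scaled to hepatocyte markers, the log2 fold changes of Insr and Mttp were -0.47 and -0.30 (adjusted p = 0.360 and 0.490).

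**Figure D2:**
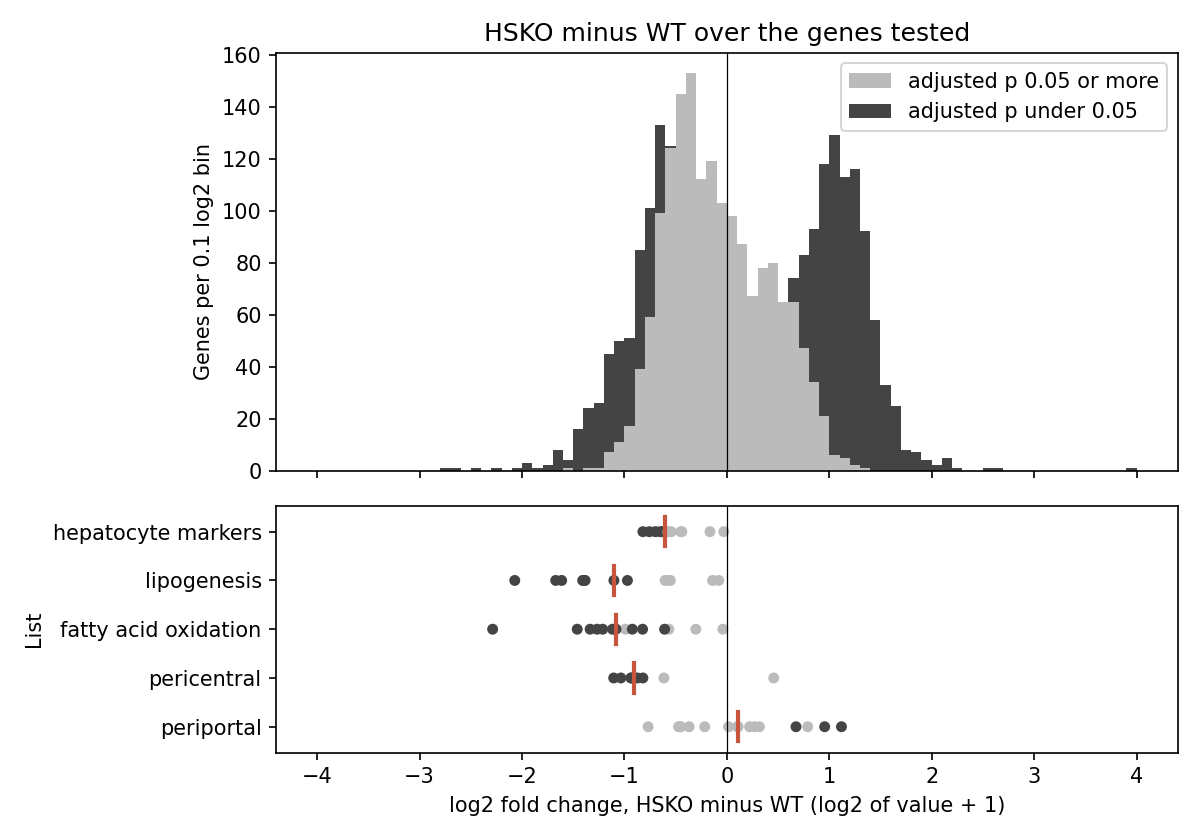
Top, number of genes per bin of 0.1 in log2 fold change (HSKO minus WT) for the 2750 genes tested, with those at an adjusted p under 0.05 in dark grey. Of these, 1 row beyond 4 is drawn in the last bin. Bottom, the tested members of 5 fixed lists, dark where called, with the list median as a vertical bar. Among bins below 0, that with most genes lies at -0.35, and in a separate search of higher bins at 1.05. Whether the distribution has more than 1 peak was not tested. The medians of hepatocyte markers and lipogenic genes are -0.60 and -1.10.

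Most measured genes of fatty acid oxidation were lower as well. Of 15 measured targets of PPARalpha and enzymes of fatty acid oxidation, 11 were lower and 0 higher, also adjusted over the list alone. Fabp1, the liver fatty acid binding protein, fell from 1844 ± 99.5 to 772 ± 123 (SD, n = 3, log2 fold change -1.27, SE 0.23, adjusted p = 0.000736). The oxidation enzymes Acadm and Hadha, named after their values were seen, had log2 fold changes of -1.21 and -1.09. The list median was -1.08 (camera adjusted p = 1.11e-05, 0.183 as the adjusted p with an estimated correlation). Against the fixed lists only, the list remained below the others (adjusted p = 0.0435). With scaling to hepatocyte markers, Plin2 and Fabp1 were lower, and with the other 4 scalings 12 to 14 of the 15.

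Some bile acid and lipoprotein genes were lower in HSKO livers, as were 6 of the 13 hepatocyte markers (median -0.60). The bile salt export pump Abcb11 fell from 69.8 ± 14.2 to 27.3 ± 1.53 and apolipoprotein B, Apob, from 564 ± 97.6 to 308 ± 40.1 (SD, n = 3, adjusted p = 0.00106 and 0.00658). Of 17 measured genes of bile acid synthesis and transport, 7 were lower (median -0.62), and of 20 genes of apolipoproteins and lipoprotein handling, 8 were lower (median -0.67), with 0 higher in both and the same counts adjusted over the list alone. At an unadjusted p below 0.05, limma also had 0 higher in both. With adjustment, edgeR and DESeq2 called 0 higher in both. Camera adjusted p was 0.000258 for both lists, and with an estimated correlation the adjusted p was 0.183 and 0.237. Scaled to hepatocyte markers, the medians were -0.08 and -0.13, with 3 bile acid genes and 0 lipoprotein genes lower and 2 bile acid genes higher, Cyp7a1 (adjusted p = 0.00812) and Slc27a5 (0.0230). Apob was not called with that scaling (log2 fold change -0.32, adjusted p = 0.402). With upper quartile scaling, quantile normalization, TMM and total reads, lower members numbered 13, 12, 12 and 14 of the 17 bile acid genes and 16, 16, 15 and 18 of the 20 lipoprotein genes.

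Some endoplasmic reticulum chaperones and acute phase proteins were lower, as were 6 of the 13 hepatocyte markers (median -0.60). Hspa5, the main chaperone of the endoplasmic reticulum, was at 90.3 ± 8.80 in WT and 50.5 ± 2.40 in HSKO, and Pdia4, a disulfide isomerase, at 32.1 ± 6.71 and 11.0 ± 8.42 (SD, n = 3, adjusted p = 0.0107 and 0.00330). Of 14 genes of the unfolded protein response, 5 were lower (median -0.58, camera adjusted p = 0.00533), and of 15 acute phase proteins, 7 were lower and 1 higher (median -0.66, camera adjusted p = 0.00402). The adjusted p with an estimated correlation was 0.237 and 0.416. Scaled to hepatocyte markers, 0 members of either list were lower, 2 and 1 were higher and the medians were -0.036 and -0.12. In upper quartile scaling, quantile normalization, TMM and total reads, lower members numbered 10, 8, 8 and 12 in the first list and 10, 10, 12 and 11 in the second. Adjusted over the list alone, 5 were lower in the first list, and 9 lower and 1 higher in the second. Orm1, an acute phase glycoprotein, was at 119 ± 43.5 and 56.7 ± 10.8, while the metallothionein Mt1 was higher at 33.8 ± 15.6 against 13.6 ± 6.72. Without WT replicate 2 the adjusted p of Hspa5 was 0.0565, and without HSKO replicate 3 that of Mt1 was 0.0579. Scaling to hepatocyte markers left Hspa5, Pdia4 and Orm1 at log2 fold changes of -0.28, -1.14 and -0.47 (adjusted p = 0.472, 0.0550 and 0.272), and scaling to total reads left Mt1 at 0.58 (adjusted p = 0.193).

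Pericentral and periportal genes are expressed at opposite ends of the liver lobule. Of 8 pericentral genes, 6 were lower, among them Oat, the ornithine aminotransferase, at 84.8 ± 7.53 in WT and 40.98 ± 16.1 in HSKO, and the cytochrome Cyp2e1 at 1395 ± 17.96 and 801 ± 161 (SD, n = 3, adjusted p = 0.00509 and 0.00939). Of 16 periportal genes, 3 were higher and 0 lower: Pck1, Sds and Pigr, which carries immunoglobulin A into bile and rose from 1436 ± 65.2 to 2802 ± 391 (adjusted p = 0.00339). Counts adjusted over each list alone were the same. Higher and lower periportal genes numbered 1 and 5 with upper quartile scaling, 1 and 5 with quantile normalization, 2 and 4 with TMM, 0 and 6 with total reads, and 5 and 0 with scaling to hepatocyte markers. Medians were -0.90 for pericentral genes (camera adjusted p = 0.00473, 0.237 as the adjusted p with an estimated correlation) and 0.11 for periportal genes, which camera did not pass (adjusted p = 0.820, 0.869 as the adjusted p with an estimated correlation). Against the fixed lists only, camera placed periportal genes above the others (adjusted p = 0.00695), and with scaling to hepatocyte markers fry passed them (FDR 0.000382). The median of all genes tested was 0.62 with that scaling, so this pass of fry does not set periportal genes apart from other genes. With that scaling 0 of the 8 pericentral genes were lower and 1 higher (median -0.36), with adjusted p of 0.184 for Oat and 0.507 for Cyp2e1, itself a hepatocyte marker. Pigr was called in 4 of the 6 scalings, with an adjusted p of 0.309 in quantile normalization, and Pck1 in 2. The periportal median was -0.18, -0.11, -0.12 and -0.57 with upper quartile scaling, quantile normalization, TMM and scaling to total reads, and 0.65 with scaling to hepatocyte markers. Cyp2e1 had an adjusted p of 0.0567 without HSKO replicate 3.

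Of 12 genes of xenobiotic metabolism, 4 were lower and 1 higher (median -0.54, camera adjusted p = 0.0201, 0.237 as the adjusted p with an estimated correlation). Cyp2c29 fell from 139 ± 17.97 to 68.4 ± 4.44, in a row that also names a pseudogene, and Nr1i3, which encodes the receptor CAR, rose from 39.0 ± 1.94 to 97.0 ± 22.4 (SD, n = 3). Of 8 male-biased liver genes, 4 were lower (median -0.61, camera adjusted p = 0.0201, 0.296 as the adjusted p with an estimated correlation), with Hsd3b5 at 42.1 ± 9.87 and 17.9 ± 7.44. Lipid droplet genes had 1 of 6 lower, Plin2 (median -0.48, camera adjusted p = 0.0465, 0.237 as the adjusted p with an estimated correlation). Nuclear genes of oxidative phosphorylation had 2 of 16 lower, Atp5a1 and Sdha (median -0.47, camera adjusted p = 0.00976, 0.237 as the adjusted p with an estimated correlation), with 0 of 16 adjusted over the list alone. At an unadjusted p below 0.05, limma had 4 of the 16 lower. With adjustment, edgeR called 5 and DESeq2 1, while 7 were lower with upper quartile scaling, 3 with quantile normalization and 13 with total reads (median -1.15). Adjusted over the list alone, the other counts were the same. Atp5a1 (adjusted p = 0.0201) was not called without WT replicate 2 (0.0669), WT replicate 3 (0.0661) or HSKO replicate 2 (0.0525), and Sdha (0.0252) not without WT replicate 3 (0.0841), HSKO replicate 1 (0.128) or HSKO replicate 3 (0.0748). With no filter, adjusted p was 0.0628 for Atp5a1 and 0.0725 for Sdha. Scaled to hepatocyte markers, the medians of these 4 lists were 0.004, -0.06, 0.06 and 0.07. In upper quartile scaling, lower members of the first 3 numbered 7, 6 and 3, and with total reads 10, 7 and 5. Scaling to hepatocyte markers ended the calls of Cyp2c29 (log2 fold change -0.46, adjusted p = 0.201), Hsd3b5 (-0.69, 0.126), Atp5a1 (-0.19, 0.635) and Sdha (-0.34, 0.472). Scaling to total reads ended that of Nr1i3 (0.59, 0.0855).

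Of 5 insulin signalling genes, Tsc2 and Gsk3a were higher and Insr lower (median -0.50, 0.04 with scaling to hepatocyte markers, camera adjusted p = 0.846, 0.869 as the adjusted p with an estimated correlation), and 2 were higher and 2 lower adjusted over the list alone. Total reads gave 1 higher and 3 lower insulin signalling genes, and scaling to hepatocyte markers 2 and 0. Tsc2, an inhibitor of the mTOR pathway, rose from 74.6 ± 14.3 to 207 ± 55.6 (SD, n = 3, adjusted p = 0.000710). The call of Gsk3a (adjusted p = 0.0163) was lost without WT replicate 2 (0.0598), WT replicate 3 (0.0608) or HSKO replicate 2 (0.0716), and with upper quartile scaling (0.0752), quantile normalization (0.0528), no filter (0.0590) or scaling to total reads (log2 fold change 0.20, adjusted p = 0.579). The adjusted p of Insr was 0.133, 0.0612 and 0.0656 without WT replicate 2, WT replicate 3 and HSKO replicate 3, and 0.360 with scaling to hepatocyte markers. Of 3 cell cycle genes, the mitotic kinase gene Aurka and the cyclin gene Ccna2 were higher, also adjusted over the list alone, at 54.1 ± 2.80 against 17.7 ± 5.70 and 53.3 ± 11.9 against 18.9 ± 4.80, and both were called in all 6 scalings. The list median was 1.45 (camera adjusted p = 0.0680, 0.323 as the adjusted p with an estimated correlation). Camera against the fixed lists only, chosen after seeing the data, placed the cell cycle genes above the others (adjusted p = 0.000778). Fry passed them (FDR 0.0236, 0.0335 with scaling to hepatocyte markers, where the median of all genes tested was 0.62). These passes rest on the 3 tested genes of 23 listed, of which 21 had a row, so they do not describe the cell cycle list as a whole.

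In glycogen metabolism, 1 gene of 5 was lower, the glycogen phosphorylase Pygl (adjusted p = 0.0281), and in cholesterol trafficking 1 of 4, the lysosomal lipase Lipa (adjusted p = 0.0306), both also adjusted over the list alone. Medians were -0.46 and -0.79 (camera adjusted p = 0.146 and 0.154), and that of glycogen metabolism was 0.08 with scaling to hepatocyte markers. Pygl was not called without WT replicate 1 (adjusted p = 0.0877), HSKO replicate 1 (0.0583) or HSKO replicate 3 (0.0856), and Lipa not without WT replicate 2 (0.174) or WT replicate 3 (0.154). Glycogen genes had 2 of 5 lower with TMM and 5 of 5 with total reads (median -1.14), and cholesterol trafficking 3 of 4 with upper quartile scaling, TMM or total reads. With no filter, adjusted p was 0.0817 for Pygl and 0.0654 for Lipa, and 0.0901 for Lipa in DESeq2. Lipa was also not called with quantile normalization (adjusted p = 0.0505), nor Pygl with no trend (0.0553). Neither was called with scaling to hepatocyte markers (log2 fold changes of -0.18 for Pygl, with an adjusted p of 0.704, and -0.67 for Lipa). Of 6 clock genes, limma called 0, also adjusted over the list alone, with 2 lower at an unadjusted p below 0.05, while edgeR called 2 lower and DESeq2 0, upper quartile scaling 2 lower, total reads 3 lower and scaling to hepatocyte markers 1 higher (median -0.41, 0.13 with scaling to hepatocyte markers, camera adjusted p = 0.333). Of 26 ribosomal proteins, 1 was higher and 0 lower (median -0.20, 0.35 with scaling to hepatocyte markers, camera adjusted p = 0.0903). At an unadjusted p below 0.05, limma had 1 higher and 2 lower, and 0 were called adjusted over the list alone. With adjustment over all genes, edgeR called 1 higher and 3 lower and DESeq2 1 higher. Ribosomal proteins had 0 higher and 15 lower with total reads (median -0.87), 0 and 5 with upper quartile scaling, and 4 and 0 with scaling to hepatocyte markers. Of 2 other ABCA and ABCG transporters, limma and DESeq2 called 0, with 0 at an unadjusted p below 0.05, while edgeR called 1, upper quartile scaling 1 and total reads 2.

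Few markers of other liver cell types were measured at this depth. Of the 13 marker lists, those of macrophages, of stellate cells and fibroblasts and of erythroid cells had a gene above the filter besides that of hepatocytes. The macrophage marker Cd5l was lower at 6.46 ± 3.62 in HSKO against 15.4 ± 5.94 in WT (SD, n = 3, adjusted p = 0.0442), and Marco, another, was at 15.1 ± 11.5 against 8.77 ± 9.27 (adjusted p = 0.219). Dcn, a marker of stellate cells and fibroblasts, fell from 19.5 ± 1.40 to 7.07 ± 2.92 (adjusted p = 0.00626). The fibronectin gene Fn1, the 1 measured member of the matrix list, was lower at 139 ± 52.5 against 214 ± 17.4 (adjusted p = 0.0470). Rad23b, near Abca1 on chromosome 4, was lower at 11.4 ± 6.51 against 24.0 ± 1.28 (adjusted p = 0.0153). Cd5l was also called adjusted over the 2 tested members of its list. Dcn, Fn1 and Rad23b were each the 1 tested member of theirs, where that adjustment changes nothing. Cd5l was not called without WT replicate 2 (adjusted p = 0.248), WT replicate 3 (0.125), HSKO replicate 1 (0.108) or HSKO replicate 2 (0.106), and Rad23b not without WT replicate 2 (0.0554) or HSKO replicate 1 (0.0628). Fn1 was called without HSKO replicate 1, with adjusted p between 0.0598 without WT replicate 3 and 0.245 without HSKO replicate 3 for the other 5 libraries. In DESeq2 the adjusted p of Cd5l, Fn1 and Rad23b was 0.139, 0.0678 and 0.0948, with no filter it was 0.0946, 0.114 and 0.0517, and in quantile normalization that of Cd5l was 0.0525. With scaling to hepatocyte markers, log2 fold changes were -0.63 for Cd5l, -0.86 for Dcn, -0.14 for Fn1 and -0.59 for Rad23b (adjusted p = 0.290, 0.0890, 0.786 and 0.254). The early response gene Junb, in a row that also names a second transcript, had a log2 fold change of 0.92 (adjusted p = 0.0586). As Junb was the 1 tested member of its list, its pass adjusted over the list alone was only its unadjusted limma p (0.0249). It was called with scaling to hepatocyte markers (adjusted p = 0.00920), with robust estimation and without WT replicate 1 (0.0296) or WT replicate 2 (0.0386). The 1 measured interferon response gene, Stat2, and the 1 erythroid gene were not called (log2 fold changes of 0.49 and 0.07, both negative with scaling to total reads). Stat2 was called higher with scaling to hepatocyte markers (log2 fold change 1.03, adjusted p = 0.0284). No member of the inflammatory cytokine, female-biased or sex chromosome lists passed the filter.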

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

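Scaling to hepatocyte markers, scaling to total reads and camera against the fixed lists only were chosen after the result was seen; the other alternatives were planned. Abca1 was lower and called in every alternative that tested it, with log2 fold changes between -3.29 and -1.24 (pseudocount 10), and lay below the filter at a minimum mean of 50. The number of genes called lower, 320, was 211 with no filter, 703 with upper quartile scaling, 502 with quantile normalization, 490 with array weights, 161 with DESeq2, 601 with edgeR, 27 with hepatocyte scaling and 1093 with total reads, where 212 were higher. With a minimum mean of 50, where 688 genes were tested, 509 changed, 391 higher and 118 lower. Leaving out 1 library gave 157 to 313 lower genes, with 159 without WT replicate 2 and 157 without WT replicate 3. Lower lipogenic members numbered 5 with DESeq2, 4 with hepatocyte scaling and 13 with total reads, against 8, and lower cholesterol members 2 with hepatocyte scaling, against 6. Lower members of the list of gluconeogenesis and FOXO1 targets, 2, numbered 4 with upper quartile scaling, quantile normalization and total reads. They numbered 0 with no filter, a minimum mean of 50, DESeq2, hepatocyte scaling and without WT replicate 3. Without WT replicate 2 or HSKO replicate 2 they numbered 1. The lipogenic median of -1.10 was past the threshold in camera in each alternative that gave a value except with an estimated correlation (adjusted p = 0.183) and against the fixed lists (0.180). The cholesterol median was not past it with DESeq2 (-1.23), total reads (-1.84), an estimated correlation (-1.16, adjusted p = 0.237) or the fixed lists (-1.16, 0.946). The median of LXR targets was -0.61 with no filter, -0.22 with upper quartile scaling, -0.32 with quantile normalization, -0.13 with edgeR and -0.59 with total reads. That of gluconeogenesis and FOXO1 targets was 0.68 at a minimum mean of 50 and 0.18 with hepatocyte scaling. Log2 fold changes changed sign for Cyp7a1 (-0.22) and Pck1 (-0.002) with total reads, Abcg8 (0.29) and Ugp2 (0.084) with hepatocyte scaling, and Marco (-0.041) with array weights. That of G6pc was -0.066 with upper quartile scaling, -0.043 with edgeR, -0.46 with total reads and -0.066 to 0.42 with 1 library left out. With the deposited scaling Pck1 was called among these genes; Cyp7a1 was called with hepatocyte scaling (adjusted p = 0.00812), Abcg8 with total reads (0.0402) and Ugp2 with edgeR (0.0422), total reads (0.0146) and without WT replicate 1 (0.0258). With hepatocyte scaling, 24 of the 67 named genes lost a call, and 19 lost one when some single library was left out. Fewer genes tested account for the smaller counts at a minimum mean of 50, where the lipogenic and cholesterol lists had too few members for a value; the cause was not tested for the rest. The replicate numbers did not pair the samples, as same-numbered deviations correlated at -0.026, -0.027 and -0.021 and no sample correlated best with its own number; the replicate block gave 1020 genes, 751 higher and 269 lower, with adjusted p of 0.0533 for Cd5l and 0.0529 for Fn1. Depth limits low genes, since 1 read is worth 1.33 to 1.46 units in HSKO.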

Other observations

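The thinning test and the count of splits were set before their results were seen; the tests of library composition, of GC content and length, of lipogenic genes against hepatocyte markers and of periportal against pericentral genes were chosen only after. One row, AB343394, named only by a sequence record and chosen after its values were seen, had 0, 2 and 2 reads in WT and 146, 165 and 345 in HSKO, a ratio of 355 with an exact 95% interval of 138 to 1308 for counting error. The share of genes called higher increased with expression, from 12.6% of genes with a mean of 10 to 25 to 66.9% of those at 300 or more, while the share called lower lay between 9.8% and 14.3%.

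Many abundant genes, Cep85 and Rad9b among them, were called higher in HSKO (783 of 1103 calls). Thinning every library to 275313 reads outside the top row kept 92.5% of the higher calls (median of 5 draws), which argues against depth as the whole cause. A difference in library composition that also varies among controls is a candidate explanation: across 2750 genes, which are not independent, WT replicate 3 minus WT replicate 1, 2 control libraries, correlated with HSKO minus WT replicate 2 at r = -0.531 (rho = -0.586), and 92.2% of the higher genes were lower in WT replicate 3 than in WT replicate 1. Of the lower genes, 73.8% were higher in WT replicate 3 than in WT replicate 1. The share over all genes tested was not computed. A correction for GC content and length kept 94.8% of the 594 higher genes that have both values, but these are 75.9% of the higher genes, so that test is void, and the deletion itself stays open as a cause. Of the 10 splits of the 6 samples 3 against 3, 1, the real one, gave as many changed genes (1103 against 0 in limma at most for the others, 111 at an unadjusted p below 0.05), too few splits for a share under 0.05.

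Fasn, Scd1 and other lipogenic genes were lower in HSKO. A lower share of hepatocyte mRNA could lower them, but relative to the hepatocyte markers the list was lower still, by a log2 difference of -0.501 (SE 0.129, exact two-sided permutation p = 0.1, the smallest possible), at 0.25 ± 0.159 in WT and -0.25 ± 0.157 in HSKO (SD, n = 3). This argues against a uniform loss of hepatocyte mRNA as the whole cause only if expression level does not account for the gap. The lipogenic genes and the markers were not matched for level. Over all genes tested, the median log2 fold change was -0.137 at means of 10 to 25 and 1.096 at 300 or more. The fall was not particular to lipogenic genes. Genes of fatty acid oxidation also lay lower relative to those markers, by -0.463 (SE 0.111, exact two-sided permutation p = 0.1). Periportal genes lay higher, by 0.659 (SE 0.027), near the median of all genes tested with scaling to those markers (0.618). With scaling to those markers, fry passed fatty acid oxidation (FDR 0.0419) and not the lipogenic list (FDR 0.122). With the deposited scaling, camera did not pass the lipogenic list against the fixed lists (adjusted p = 0.180). The composition difference among controls and an effect of the deletion both stay open. The mean log2 deviation of the lipogenic list was 0.44 in WT replicate 1 and 0.50 in WT replicate 3. Relative to the hepatocyte markers it was 0.291 and 0.075, but 2 single libraries exclude nothing.

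Periportal genes such as Pigr lay above pericentral genes such as Oat in HSKO, with a log2 difference of 0.847 (SE 0.254, exact two-sided permutation p = 0.1, the smallest possible) relative to WT. It was higher in WT replicate 3 than in WT replicate 1 by 0.369, while library composition would make it lower there, but a single library on each side does not give the spread between samples (WT SD 0.185), so that test of library composition is void. Library composition, a shift in lobular zonation and other effects of the deletion all stay open as causes, as hepatocyte states were not measured apart.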
